A study of Mus musculus with 12 samples.

How the data were processed

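RNA of B16 cells, an established mouse melanoma line, was measured on 12 Illumina mouse bead arrays. The labels gave 6 days of a culture cycle (0, 4, 8, 12, 16 and 20) with 1 array of set 1 and 1 array of set 2 on each day, and the design text of the series called the sets consecutive cycles. Days 4, 8 and 12 were labelled pigmented and days 0, 16 and 20 depigmented. Per the labels' protocols, cells were seeded at 100 cells per cm2, harvested on days 4, 8 and 12, and replated on day 12 at 10000 cells per cm2 for the harvests of days 16 and 20, so that the pigmentation label could not be told apart from time in culture and seeding. A separate density label of each array did not follow that protocol: day 8 and day 12 of set 1 were marked high, for example, and day 16 low. It was used as a term in 1 alternative model and in 1 test of seeding density. Nothing in the labels said that the 2 arrays of a day came from separate cultures beyond the word cycle, so p-values measure only the spread between these arrays, which may be technical.

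The deposited signal table gave a linear intensity per probe, summarized over beads, and a detection p-value for each of 45281 probes, per the file headers. The detection p-values were multiples of 1 over 936, the number of negative controls this implied. The authors' value table held linear intensity values in which each column was an exact straight-line transform of 1 signal column, with every array mean at 280.64 and values below 0 present, as found from the values. Its direction and scale were thus settled. Column medians of that table lay between 6.26 and 8.71. For days 4, 12 and 20, the set numbers of the 6 columns were exchanged between the 2 tables, while the days were not. The set numbers of the signal table were used, and those of the value table, and its values with the signal table's set numbers, were alternatives chosen after seeing the data. Software and array version behind the deposited tables were not given in the sources used here, and no coordinates are printed. Processing of this kind limits what can be read from weak probes, since bead summaries without negative control values leave the background to be estimated from the detection p-values.

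Signals were corrected for background and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with background parameters inferred from the detection p-values and an offset of 16. Probes detected at p under 0.05 on at least 2 arrays numbered 22978. Platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378, and a probe with several names was not named. The RefSeq table listed the gene of 34807 of the named probes and updated 0 symbols. Of the detected probes, 19120 had 1 symbol and 3858 had none. Each gene was represented by its probe with the highest mean over the 12 arrays, which left 11470 genes, 4889 of them with more than 1 detected probe. Such a choice favours bright probes, whose changes can be compressed near saturation, and values of other probes are given for some pigment genes.

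Changes were tested on the log2 scale with limma's lmFit and eBayes with an intensity trend, with day as a factor over all 12 arrays, and Benjamini-Hochberg adjustment within each comparison at 0.05. A model with 2 groups was used for pigmented against depigmented, so that its spread included that between days. A model with day and set was used for the sets. All p-values are two-sided. Where no probe of a gene was detected on any array of 1 group, its change is given as a bound: the mean of the detected group over the mean, per array, of the higher of the lowest detected normalized value and the probe's own value. Each such bound is worded as at least N-fold and holds under the main normalization only. A list's median is also given with such genes at their bound where this changed the printed value.

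Before the data were examined, 27 gene lists were fixed: pigment synthesis and melanocyte identity, melanosome biogenesis and transport, interferon response, antigen presentation, G2 and M phase, DNA replication, glycolysis, hypoxia response, sterol synthesis, fatty acid synthesis, fatty acid oxidation, oxidative phosphorylation, amino acid starvation and ATF4 response, ER chaperones and unfolded protein response, lysosome and autophagy, ribosome biogenesis and MYC, p53 targets, NRF2 and metallothionein, extracellular matrix with adhesion and dedifferentiation, WNT targets, immediate early and MAPK feedback genes, cyclic AMP response, heat shock, and markers of leukocytes, fibroblasts, keratinocytes and endothelium. List members not found under their own symbol were matched through aliases, which put Pigq in place of Gpi1, Eno1b in place of Eno1 and Uqcrq in place of Uqcrb, all different genes. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The rule for named genes was fixed at the same time: the 8 largest rises and falls of each comparison among genes past the threshold whose arrays did not overlap (5 each for the sets, differing the same way on all 6 days, in that comparison), 11 pigment genes whatever their p, and up to 4 members of each list with the smallest adjusted p. Symbols of clones and predicted genes were left out of the largest changes. The further comparisons (day 8 against day 4, day 12 against day 8, day 20 against day 16) were chosen after seeing the data.

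The tests were checked on simulated data with 200 changed genes among 11470. For day 8 against day 0, 90% of genes changed by 1 log2 unit and 48% of those changed by 0.5 were recovered, with 12 false calls (8% of calls). For pigmented against depigmented the shares were 100% and 89%, with 9 false calls (4.55%). That simulation held the spread between arrays of a day but none between days. The real comparison includes the spread between days, so these shares do not carry over to it. Detected probes per array ranged from 18508 to 19780 and mean signal from 269.9 to 441, and the 2 arrays per day limit the precision.

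The labels tie the set number to a cycle, so it was treated as pairing arrays and a model with the set as a replicate block was an alternative. Over 15 pairs of days, deviations of set 1 from the day means correlated between -0.0293 and 0.267 across genes, above 0.1 for 8 pairs. With the value table's set numbers they correlated between -0.267 and 0.112, above 0.1 for 2 pairs, and which numbering is right was not settled. Alternatives covered the background correction, the normalization, the value table, the detection filter, the choice of probe, the eBayes trend, array weights, the replicate block, the arrays in the fit, the density label as a term, each array left out in turn and the correlation in camera. A planned block by chip was not run, because the tables gave no chip barcode. Leaving out both day 20 arrays and both day 8 arrays were alternatives chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.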

Results

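B16 melanoma cells, which make melanin in culture, were profiled over 6 days of a cycle in which they gained and lost pigment, to follow the genes that changed with pigmentation. Each day had 2 arrays, 1 of each set, and values below are log2 changes with their standard error (SE) from limma, n = 2 arrays per day unless stated. The arrays of a day correlated at 0.995 to 0.996 across the genes tested, after normalization. Of 11470 genes, 9720 (84.7%) changed over the 6 days. Against day 0, the number of genes past the threshold was 7284 on day 4, 7242 on day 8, 6000 on day 12, 5457 on day 16 and 7795 on day 20. By at least 2-fold, the counts were 2289, 2295, 1041, 753 and 2994. Principal components of the 12 arrays placed 52.2% of the variance on the first axis, along which both day 20 arrays lay at one end (-75.6 and -76.3) and the 4 arrays of days 4 and 8 at the other (41.3 to 42.1).

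**Figure D1:**
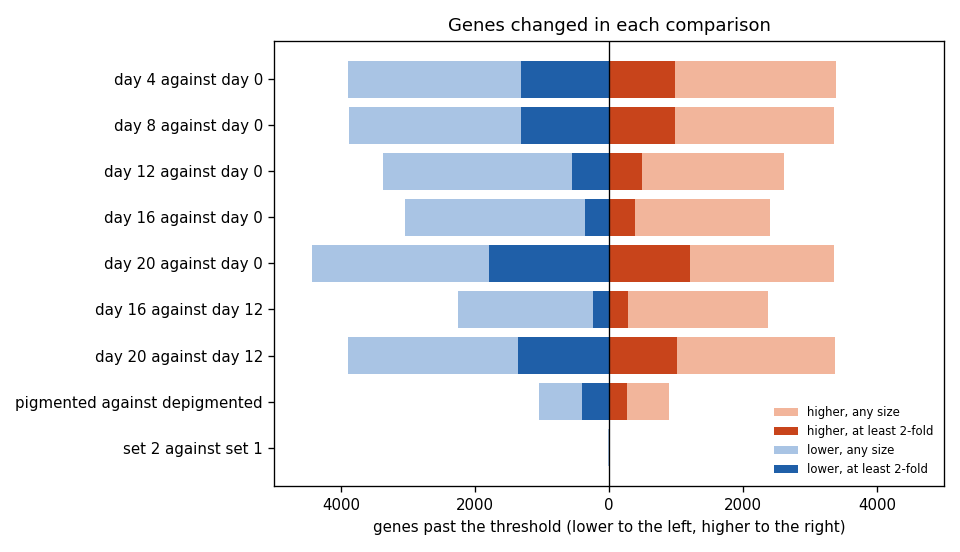
Genes past the threshold in each comparison (limma, adjusted p under 0.05), lower to the left and higher to the right of the axis, with changes of at least 2-fold in the darker colour. Day 20 against day 0 had the most genes in this plot (7795), and set 2 against set 1 had 24.

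Pigment genes were strongly higher on day 8 than on day 0. Tyr, the rate-limiting enzyme of melanin synthesis, rose by 3.89 ± 0.11, Slc45a2, a melanosomal transporter, by 3.91 ± 0.07, Gpr143, a melanosomal receptor, by 4.34 ± 0.11, Pmel, the scaffold protein of melanosomes, by 3.03 ± 0.07, and Mlana by 2.97 ± 0.08. Mitf, the central transcription factor of melanocytes, rose by 1.53 ± 0.12 and Mc1r, the melanocortin receptor, by 1.64 ± 0.12, while Oca2 was at least 3.15-fold and Slc24a5 at least 1.91-fold higher. Without background correction their log2 changes were 1.07 for Oca2 and 0.50 for Slc24a5, below these bounds but still called. On the pigment list 19 of 21 measured genes rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 1.53 (camera adjusted p = 1.58e-10). Smaller rises of Tyrp1 (0.33 ± 0.08) and Dct (0.44 ± 0.08), which encode melanin enzymes, came from bright probes, and other probes gave 2.46 and 3.25 for Tyrp1, 1.48 for Dct, 4.88 for Pmel and 3.48 to 6.39 for Slc45a2. A second Mitf probe, detected on 3 arrays, gave -0.11 on day 8. The call of Tyrp1 was lost with the authors' value table (0.26, adjusted p = 0.0672) and without set 1 of day 0 (0.18, adjusted p = 0.0927).

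**Figure D2:**
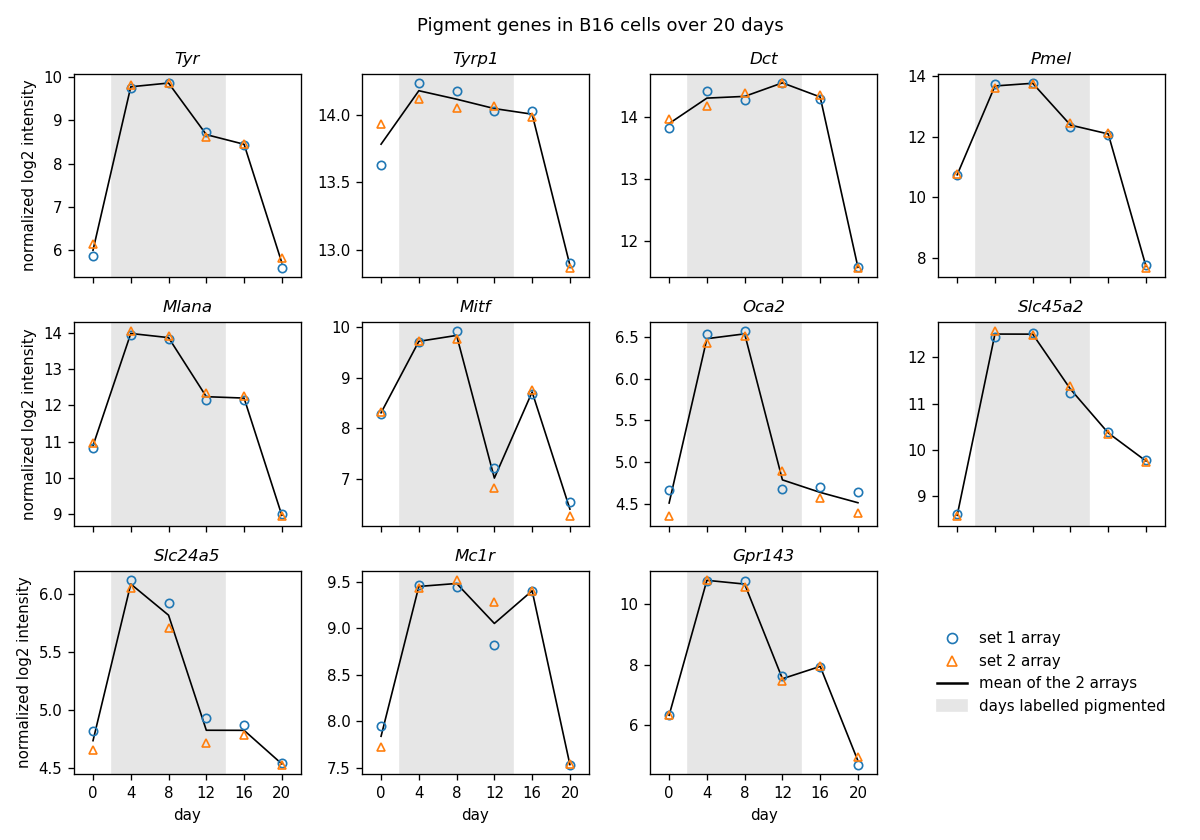
Normalized log2 intensity of the 11 pigment genes (y axes, scaled per gene) by day (x axes), with each array as a point, the mean of the 2 arrays as a line and the days labelled pigmented in grey. Tyr and Pmel were highest on days 4 and 8, and Mitf lay below its day 0 level on day 12 (-1.29).

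Melanosome transport genes moved with the pigment genes on day 8. Of 25 measured melanosome genes 15 rose and 5 fell (median 0.65, camera adjusted p = 0.00235), among them Rab27a (1.75 ± 0.07), Rab32 (2.14 ± 0.10), Hps3 (1.78 ± 0.09) and Myo5a (1.51 ± 0.08). Other large rises were of Cck, which encodes cholecystokinin (at least 48.6-fold), ND4L, a mitochondrially encoded subunit of complex I (4.70 ± 0.13), Eps8 (4.13 ± 0.10), Slc7a11, a cystine transporter gene on the pigment list (4.06 ± 0.12), and cyclin E2, Ccne2 (at least 10.9-fold). Lcn2, which encodes lipocalin 2, fell the most (-5.89 ± 0.13), with the immediate early genes Fosb (-5.35 ± 0.13) and Egr1 (-4.99 ± 0.08), Prph (-5.26 ± 0.11), the chemokine gene Ccl5 (-4.74 ± 0.09) and Slpi (-4.54 ± 0.09). H2-Ab1, a class II antigen-presenting chain, was at least 27.2-fold lower.

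Interferon and antigen presentation genes were lower on day 8 than on day 0. Of 39 measured interferon response genes 35 fell and 2 rose, with a median of -1.45 (camera adjusted p = 9.17e-11), and Dhx58 (-4.27 ± 0.09), Isg15 (-3.38 ± 0.10), Ifit3 (-2.83 ± 0.07) and Rsad2 (-2.26 ± 0.07) led the list. Antigen presentation genes fell in 14 of 19 cases and rose in 2 (median -1.05, camera adjusted p = 8.96e-05), including Psmb8 (-2.05 ± 0.09) and H2-K1 (-2.21 ± 0.10). Immediate early and MAPK feedback genes had a median of -1.91, with 17 of 23 lower and 4 higher (camera adjusted p = 1.62e-05). The cyclic AMP response list had 6 of 11 lower and 2 higher (median -0.96, camera adjusted p = 0.0349, adjusted p = 0.0834 with an estimated correlation). Extracellular matrix genes had 15 of 25 lower and 3 higher (median -0.48, camera adjusted p = 0.00443, adjusted p = 0.0834 with an estimated correlation), with Ccn1 at -3.21 ± 0.08 and Axl at -2.58 ± 0.08 but Sox9 at 2.83 ± 0.08.

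Metabolic and growth lists also separated day 8 from day 0. On the glycolysis list 17 of 20 measured genes fell and 1 rose (median -1.08, camera adjusted p = 1.4e-06), including Pfkl (-2.62 ± 0.08) and Aldoa (-2.03 ± 0.09). Among the 20 was Pigq (0.14 ± 0.11, not past the threshold), which is not a glycolysis gene and was matched through an alias it shares with Gpi1. The glycolysis median was also below day 0 on the depigmented arrays of day 16 (-0.66 and -0.52) and day 20 (-1.01 and -1.07). Its fall was thus not limited to pigmented days. Hypoxia response genes fell in 18 of 22 cases and rose in 2 (median -1.17, or -1.09 with undetected genes at their bound, camera adjusted p = 2.23e-05), with Egln3 at -3.49 ± 0.11. Ribosome biogenesis genes rose in 21 of 24 cases and fell in 0 (median 0.86, or 0.77 with bounds, camera adjusted p = 2.77e-08; 21 and 1 adjusted over the list alone), led by Nop56 (2.37 ± 0.09). Chaperones of the endoplasmic reticulum rose in 18 of 20 cases (median 1.28, camera adjusted p = 3.41e-09), with Calr at 2.99 ± 0.11 and Creld2 at 2.12 ± 0.08. DNA replication genes rose in 24 of 30 cases and fell in 0 (median 0.74, camera adjusted p = 5.97e-08), including Tyms (1.58 ± 0.08) and Cdc6 (1.86 ± 0.11).

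Several stress response lists were higher on day 8. ATF4 response genes rose in 19 of 32 cases and fell in 5 (median 0.38, camera adjusted p = 0.00235), with Phgdh, an enzyme of serine synthesis, at 2.72 ± 0.10. Heat shock genes rose in 9 of 14 cases and fell in 1 (10 and 1 adjusted over the list alone; median 0.54, camera adjusted p = 0.0023), led by Hsph1 (3.20 ± 0.08). NRF2 targets rose in 11 of 19 cases (median 0.40, camera adjusted p = 0.00371, adjusted p = 0.0923 with an estimated correlation), with Gclm at 2.94 ± 0.08. The p53 list had 12 of 19 higher and 5 lower (median 0.49, camera adjusted p = 0.0255, adjusted p = 0.0834 with an estimated correlation). Sterol synthesis genes had 10 of 18 higher and 4 lower (median 0.74, or 0.72 with bounds, camera adjusted p = 0.0157, adjusted p = 0.0834 with an estimated correlation).

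No list shift passed on day 8 for G2 and M phase (median 0.19, or 0.13 with bounds), fatty acid synthesis (0.12), fatty acid oxidation (0.17, or 0.12 with bounds), oxidative phosphorylation (-0.13), lysosome and autophagy (0.25) or WNT targets (0.20, or 0.11 with bounds). Among markers of other cell types, 3 fibroblast genes were measured, and Pdgfra was at least 3.32-fold and Col1a1 at least 1.77-fold lower, with Pdgfrb at -1.61 ± 0.17. Of 3 measured leukocyte genes, Fcer1g rose (1.41 ± 0.16) and Lyz2 fell (-0.49 ± 0.16), although Lyz2 stood at 0.21 (adjusted p = 0.188) with the mean of its probes. The keratinocyte marker Krt1 (-0.14 ± 0.19) and the endothelial marker Vwf (0.16 ± 0.19) did not pass. Counts adjusted over the list alone equalled the others for the lists of day 8 except where given, apart from G2 and M phase (10 and 4 against 11 and 4) and lysosome and autophagy (17 and 9 against 17 and 8).

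Day 4 had almost the same profile as day 8. Tyr rose by 3.80 ± 0.11, Pmel by 2.94 ± 0.07, Mlana by 3.09 ± 0.08, Mitf by 1.42 ± 0.12 and Gpr143 by 4.46 ± 0.11 over day 0, Cck was at least 45.3-fold higher and Lcn2 fell by 5.86 ± 0.13. On the pigment list 20 of 21 genes rose (20 adjusted over the list alone; median 1.42, camera adjusted p = 1.19e-10), and 35 of 39 interferon genes fell (35 adjusted over the list alone; median -1.55, camera adjusted p = 1.19e-10). Between day 8 and day 4 limma called 0 of 11470 genes, with 307 at an unadjusted p under 0.05, and Tyr differed by 0.09 ± 0.11. The standard deviation of the log2 difference across genes was 0.126 for these days, and between 0.489 and 1.104 for every other pair of days.

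On day 12, the last harvest before replating, pigment genes had come part of the way down. Tyr was 2.69 ± 0.11 above day 0, Slc45a2 2.73 ± 0.07, Pmel 1.64 ± 0.07, Mlana 1.35 ± 0.08 and Gpr143 1.21 ± 0.11, whereas Mitf fell (-1.29 ± 0.12, but -0.077 by its second probe). Oca2 and Slc24a5, each detected on 1 of 2 day 12 arrays and on 0 of 2 day 0 arrays, did not pass. On the pigment list 15 of 21 genes rose and 1 fell (15 and 1 adjusted over the list alone; median 0.73, camera adjusted p = 1.68e-08). Melanosome genes rose in 14 of 25 cases and fell in 6 (14 and 6 adjusted over the list alone; median 0.29, camera adjusted p = 0.0476), a call that was lost with the set as a block (adjusted p = 0.056) and with an estimated correlation (adjusted p = 0.0875 with an estimated correlation). The call was also lost with median centring (camera adjusted p = 0.123) and with the value table (camera adjusted p = 0.117). Interferon genes fell in 36 of 39 cases and rose in 1 (36 and 1 adjusted over the list alone; median -1.32, camera adjusted p = 7.18e-17).

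Targets of p53 rose on day 12 in 16 of 19 cases and fell in 1 (16 and 1 adjusted over the list alone; median 0.88, camera adjusted p = 2.63e-09), with Ckap2 at 2.89 ± 0.11, Trp53inp1 at 2.10 ± 0.08 and Mdm2, the ubiquitin ligase of p53, at 2.05 ± 0.08. Sterol synthesis genes fell in 13 of 18 cases and rose in 2 (13 and 2 adjusted over the list alone; median -0.62, camera adjusted p = 0.000133), including Mvd (-1.73 ± 0.13) and Fdps (-1.004 ± 0.07). Immediate early genes fell in 17 of 23 cases and rose in 2 (17 and 2 adjusted over the list alone; median -1.93, camera adjusted p = 2.17e-09), with Fosb at -5.19 ± 0.13 and Fos at -4.48 ± 0.09. The cyclic AMP response list had 9 of 11 genes lower (11 adjusted over the list alone; median -0.96, camera adjusted p = 3.87e-06). NRF2 targets had 12 of 19 genes higher and 2 lower (12 and 2 adjusted over the list alone; median 0.40, camera adjusted p = 0.000172, adjusted p = 0.0553 with an estimated correlation), with Nqo1 at 3.54 ± 0.12. Oxidative phosphorylation genes fell in 18 of 29 cases and rose in 1 (18 and 1 adjusted over the list alone; median -0.25, camera adjusted p = 0.00431). Large rises outside these lists were of Zbtb2, a zinc finger gene (3.93 ± 0.07), and Cav2, caveolin 2 (at least 13.1-fold).

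Day 16, the first harvest after replating, was labelled depigmented, yet pigment genes were still above day 0. Tyr was higher by 2.46 ± 0.11, Slc45a2 by 1.78 ± 0.07, Pmel by 1.35 ± 0.07, Mlana by 1.31 ± 0.08, Mc1r by 1.56 ± 0.12 and Gpr143 by 1.61 ± 0.11. Of 21 pigment list genes 13 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.33, camera adjusted p = 4.97e-05). Interferon genes rose in 25 of 39 cases and fell in 5 (26 and 5 adjusted over the list alone; median 0.42, camera adjusted p = 2.95e-06), led by Gbp3 (1.70 ± 0.10). DNA replication genes rose in 20 of 30 cases (21 adjusted over the list alone; median 0.73, camera adjusted p = 2.79e-11). Immediate early genes fell in 17 of 23 cases and rose in 1 (18 and 1 adjusted over the list alone; median -1.36, or -1.22 with bounds, camera adjusted p = 6.07e-12), with Fosb at -6.39 ± 0.13. The inhibitors of DNA binding Id1 (-4.52 ± 0.14), Id2 (-4.44 ± 0.08) and Id3 (-2.87 ± 0.16) were among the largest falls.

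Against day 12, interferon genes rose on day 16 while pigment genes went both ways. Interferon genes rose in 37 of 39 cases and fell in 1 (37 and 1 adjusted over the list alone; median 1.86, or 1.74 with bounds, camera adjusted p = 7.45e-34), with Oas2 at 3.73 ± 0.12, Gbp3 at 3.66 ± 0.10 and Ifit3 at 2.55 ± 0.07. Lcn2 rose by 6.003 ± 0.13, Saa3, an acute phase gene, by 4.26 ± 0.09, and the chemokine gene Cxcl2 by 4.71 ± 0.14. Antigen presentation genes rose in 14 of 19 cases (14 adjusted over the list alone; median 0.62, camera adjusted p = 1.37e-06). Tyr (-0.22 ± 0.11), Tyrp1 (-0.04 ± 0.08) and Mlana (-0.04 ± 0.08) did not pass, whereas Slc45a2 (-0.95 ± 0.07) and Trpm1, a melanocyte channel gene (-3.57 ± 0.09), fell and Mitf rose by 1.71 ± 0.12. Other Slc45a2 probes gave -0.95, -0.24 and -0.37, and the second Mitf probe, detected on 3 arrays, gave 0.087. On the pigment list 5 of 21 genes rose and 8 fell (5 and 8 adjusted over the list alone; median -0.15, camera adjusted p = 0.0332, adjusted p = 0.0772 with an estimated correlation). That list call was also lost with the value table, with probes detected on all arrays, with the mean of probes, and without set 2 of day 12 (median -0.11, adjusted p = 0.0709).

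Replating was also followed by opposite changes in stress and synthesis lists between day 12 and day 16. Targets of p53 fell in 17 of 19 cases (17 adjusted over the list alone; median -1.11, camera adjusted p = 5.9e-15), with Zmat3 at -2.01 ± 0.09, Ccng1 at -1.68 ± 0.08 and Cdkn1a at -1.11 ± 0.07. NRF2 targets fell in 11 of 19 cases and rose in 1 (11 and 1 adjusted over the list alone; median -1.11, camera adjusted p = 1.42e-08), with Nqo1 at -3.76 ± 0.12 and Gclm at -2.58 ± 0.08. Sterol synthesis genes rose in 14 of 18 cases (14 adjusted over the list alone; median 0.81, camera adjusted p = 1.34e-10), including Fdps (1.97 ± 0.07) and Cyp51 (1.52 ± 0.10). DNA replication genes rose in 27 of 30 cases (28 adjusted over the list alone; median 0.75, camera adjusted p = 6.47e-15). Extracellular matrix genes had 10 of 25 higher and 2 lower (10 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 0.0502, or 0.0418 with the set as a block). In all, 4638 genes changed, and 2833 did with median centring in place of the quantile step.

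Day 20 stood far from day 0 in its cell cycle genes. Of 24 measured G2 and M phase genes 22 fell and 0 rose (22 and 0 adjusted over the list alone; median -3.03, camera adjusted p = 6.84e-13), with Foxm1, a regulator of mitotic genes, at -4.75 ± 0.09 and the kinase gene Aurkb at -3.77 ± 0.08. Aspm, a spindle gene, was at least 17.8-fold lower. DNA replication genes fell in 28 of 30 cases and rose in 1 (28 and 1 adjusted over the list alone; median -2.20, camera adjusted p = 8.53e-11), including Mcm5 (-4.14 ± 0.08) and Tk1 (-4.11 ± 0.10). ATF4 response genes rose in 26 of 32 cases and fell in 3 (26 and 3 adjusted over the list alone; median 1.18, camera adjusted p = 2.6e-09), with Ddit3 at 4.18 ± 0.10, Trib3 at 3.42 ± 0.08 and Chac1 at 3.40 ± 0.07. Chaperones of the endoplasmic reticulum rose in 18 of 20 cases and fell in 2 (18 and 2 adjusted over the list alone; median 1.31, camera adjusted p = 1.44e-07), among them Hspa5 (3.01 ± 0.13). Zbtb2 had the largest rise (6.51 ± 0.07), and Prf1, the perforin gene, rose by 5.06 ± 0.09.

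Pigment genes on day 20 were mostly at or below their day 0 level. Pmel (-3.03 ± 0.07), Dct (-2.31 ± 0.08), Mlana (-1.92 ± 0.08) and Mitf (-1.91 ± 0.12) fell, while Slc45a2 remained higher (1.17 ± 0.07). Among the 21 pigment list genes 13 fell and 2 rose (13 and 2 adjusted over the list alone; median -0.38, camera adjusted p = 0.0209, adjusted p = 0.0773 with an estimated correlation). That median was -0.90 with probes detected on all arrays and -0.79 with median centring. Interferon genes went both ways, with 19 of 39 higher and 14 lower (19 and 14 adjusted over the list alone; median 0.26, camera adjusted p = 0.146). Both day 20 arrays had the lowest mean signals (269.9 and 273, against 303 to 441 on the other arrays). The median change of all genes was -0.11, or -0.30 with median centring, and 43.1% of the changed genes were higher, or 27.7% with median centring, so that directions on day 20 are relative to that shift.

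From day 12 to day 20, pigment genes fell and interferon genes rose. Falls were measured for Pmel (-4.67 ± 0.07), Mlana (-3.26 ± 0.08), Tyr (-2.98 ± 0.11), Dct (-2.97 ± 0.08), Gpr143 (-2.72 ± 0.11) and Trpm1 (-4.98 ± 0.09). The pigment list had 16 of 21 genes lower and 0 higher (16 and 0 adjusted over the list alone; median -1.55, camera adjusted p = 6.91e-08), and 17 of 25 melanosome genes fell while 2 rose (17 and 2 adjusted over the list alone; median -0.50, camera adjusted p = 0.00192). Interferon genes rose in 31 of 39 cases and fell in 1 (33 and 1 adjusted over the list alone; median 1.37, camera adjusted p = 8.07e-14), with Irf7 and Oasl2 both at 3.87 ± 0.12. Lcn2 rose by 6.65 ± 0.13, Slpi by 5.27 ± 0.09 and Ccl5 by 3.92 ± 0.09, and ND4L was at least 57.4-fold lower.

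Proliferation and stress lists also moved between day 12 and day 20. All 24 G2 and M phase genes fell (24 adjusted over the list alone; median -3.33, or -3.19 with bounds, camera adjusted p = 4.07e-16), with Birc5, the survivin gene, at -4.76 ± 0.09 and Aurkb at -4.55 ± 0.08. DNA replication genes fell in 29 of 30 cases (29 adjusted over the list alone; median -2.18, or -2.09 with bounds, camera adjusted p = 2.88e-14). Heat shock genes rose in 11 of 14 cases (11 adjusted over the list alone; median 0.88, camera adjusted p = 7.46e-05), with Hsph1 at 2.28 ± 0.08. The cyclic AMP response list rose in 9 of 11 cases and fell in 1 (9 and 1 adjusted over the list alone; median 1.34, or 1.096 with bounds, camera adjusted p = 0.000399), including Per1, a clock gene (2.82 ± 0.09), and Ppargc1a (2.48 ± 0.09). Across all genes, 7271 changed and 46.3% of them were higher, a share of 29.1% with median centring, which set the median gene at -0.22.

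**Figure D3:**
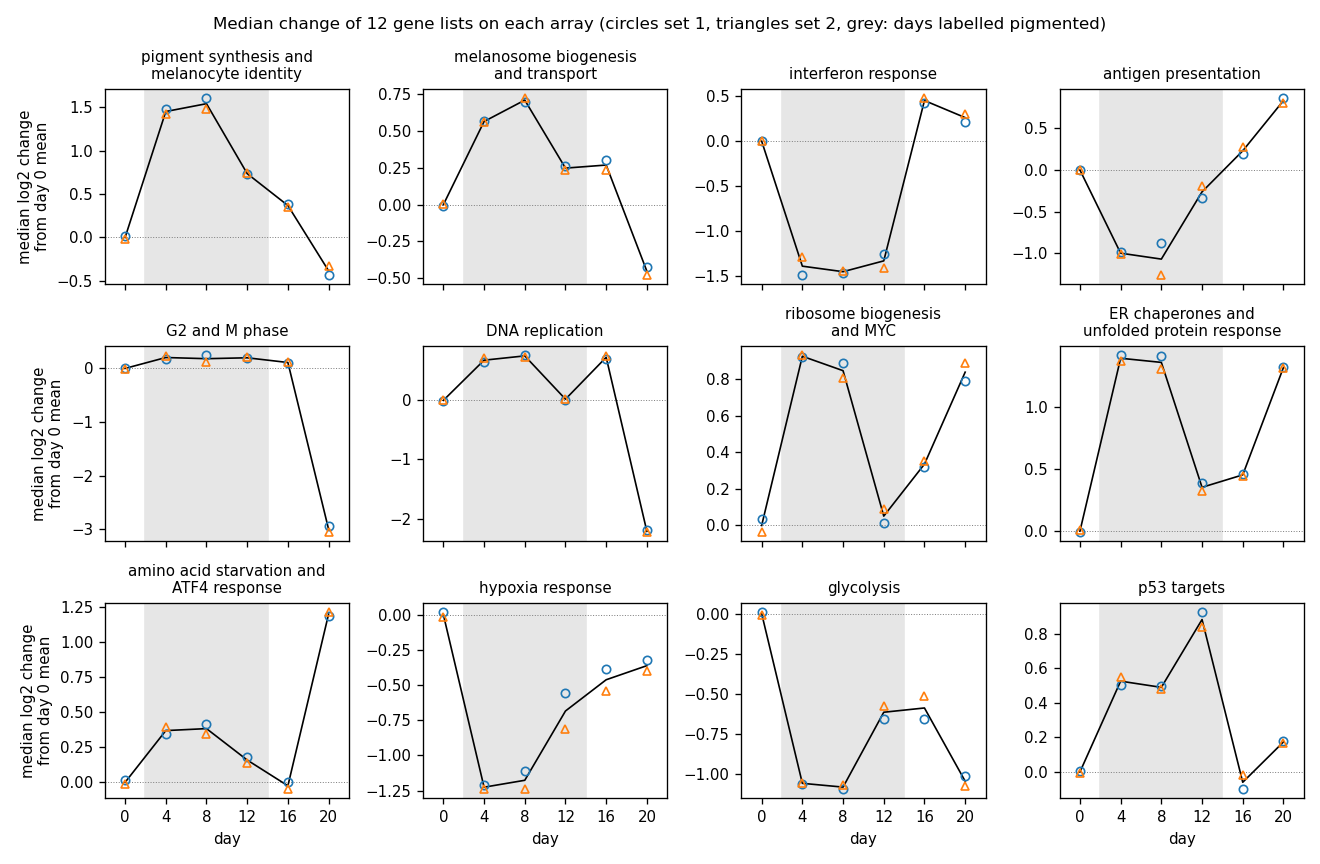
Median over the members of 12 gene lists of the log2 change from the gene's day 0 mean (y axes) by day (x axes), with circles for set 1, triangles for set 2, a line for the mean of the 2 arrays and the days labelled pigmented in grey. The interferon list lay below day 0 on the pigmented days and the G2 and M phase list fell on day 20 (list median -3.03 against day 0).

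Changes on the way to pigmentation ran partly the other way on the way back. Day 8 against day 0 and day 20 against day 12, which share no array, correlated at r = -0.162 across 11470 genes, which are not independent replicates. Of these genes 1453 rose by day 8 and fell by day 20 where independent lists would share 1142, and 1397 fell and then rose where 1141 would be shared. For the same direction the counts were 1016 genes up in both (986 for independent lists) and 1383 down in both (1322). These also lay above the counts for independent lists, though by less, so an excess over independent lists does not by itself mark a reversal.

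Arrays labelled pigmented differed from those labelled depigmented in interferon and pigment genes (n = 6 arrays each). The 2-group model counted these arrays as independent, although the 2 arrays of a day resemble each other. Between days 4 and 8 no gene was called. Arrays of a day differed by a standard deviation of 0.188 to 0.219 across genes. Days of 1 label differed by 0.540 to 0.976, except days 4 and 8 (0.126). The p-values of this comparison, those of camera below included, are thus too small, since they count arrays and not days. Lcn2 (-6.25 ± 0.21), Slpi (-4.63 ± 0.32), Ccl5 (-4.38 ± 0.40), Saa3 (-4.05 ± 0.24) and Irf7, a regulator of interferon genes (-3.86 ± 0.24), were lower. Cck was at least 24.6-fold higher, and Trpm1 (4.29 ± 0.29), Slc7a11 (3.52 ± 0.28), Slc45a2 (2.53 ± 0.37), Gpr143 (3.30 ± 0.78), Pmel (3.09 ± 0.76), Tyr (2.73 ± 0.54) and Mlana (2.67 ± 0.60) rose, with Oca2 at least 2.11-fold higher. Without background correction the log2 change of Oca2 was 0.72, below that bound but still called. Tyrp1 (0.56 ± 0.20), Dct (1.13 ± 0.48) and Mitf (1.05 ± 0.65) did not pass. Tyrp1 passed with the mean of its probes (1.504, adjusted p = 0.0157) and without either day 16 array (adjusted p = 0.0422 and 0.0477). With array weights Mitf passed (adjusted p = 0.00497) and Pmel and Tyr stood at 1.93 and 1.79, and all 3 of Tyrp1, Dct and Mitf passed when the spread was taken between arrays of 1 day. Mc1r passed at 1.07 ± 0.34 (adjusted p = 0.0497), a call that was lost under most alternatives, the set as a block included (adjusted p = 0.0686). Its change itself shrank to 0.34 with array weights (adjusted p = 0.187) and to 0.71 without both day 20 arrays (adjusted p = 0.137). Slc24a5 passed at 0.88 ± 0.23. Its call was lost without set 1 or set 2 of day 4 (adjusted p = 0.0572 and 0.0600) or of day 8 (adjusted p = 0.0596 and 0.0546), and without both day 20 arrays (adjusted p = 0.0525). Without both day 8 arrays, an alternative chosen after seeing the data that leaves fewer arrays, calls were lost for Gpr143 (2.80, adjusted p = 0.111), Pmel (2.85, adjusted p = 0.114), Tyr (2.52, adjusted p = 0.0596), Mlana (2.42, adjusted p = 0.0955), Slc24a5 (0.76, adjusted p = 0.149), Mc1r (0.99, adjusted p = 0.212) and Oca2 (adjusted p = 0.116). Their directions did not change.

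Of 39 interferon genes 33 were lower and 0 higher on pigmented arrays (35 and 0 adjusted over the list alone; median -1.38, camera adjusted p = 1.26e-29, adjusted p = 0.00248 with an estimated correlation). The pigment list had 13 of 21 genes higher and 0 lower (17 and 0 adjusted over the list alone; median 1.38, or 1.13 with bounds, camera adjusted p = 3.98e-11, adjusted p = 0.163 with an estimated correlation). Without both day 20 arrays, an alternative chosen after seeing the data, its median was 0.86 (camera adjusted p = 2.34e-09) and Pmel stood at 1.86 (adjusted p = 0.00784). Antigen presentation genes were lower in 12 of 19 cases (14 adjusted over the list alone; median -0.88, camera adjusted p = 1.19e-07, adjusted p = 0.163 with an estimated correlation). Hypoxia response genes were lower in 11 of 22 cases (12 lower and 1 higher adjusted over the list alone; median -0.61, camera adjusted p = 6.21e-06, adjusted p = 0.202 with an estimated correlation). The hypoxia median was below day 0 on the pigmented arrays of day 12 (-0.56 and -0.81). It was also below day 0 on the depigmented arrays of day 16 (-0.39 and -0.54) and day 20 (-0.33 and -0.40). Targets of p53 were higher in 8 of 19 cases and lower in 1 (9 and 1 adjusted over the list alone; median 0.50, camera adjusted p = 3.09e-05, adjusted p = 0.202 with an estimated correlation), and Ccng1 stood at 1.57 ± 0.09. G2 and M phase genes had a median of 1.08 with 2 of 24 past the threshold (0 adjusted over the list alone; camera adjusted p = 0.000121, adjusted p = 0.542 with an estimated correlation), and 0.08 (camera adjusted p = 0.307) without both day 20 arrays. Of the fibroblast markers, Col1a1 was at least 1.504-fold lower and Pdgfra stood at -1.31 ± 0.30 on pigmented arrays, and no measured leukocyte marker passed.

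In all, 1938 genes differed between the labelled states, 887 higher and 1051 lower, in limma's model of 2 groups, and 45.8% of them were higher, a share of 66.2% with median centring, which set the median gene at 0.12. The count ranged from 366 without both day 8 arrays to 7585 when the spread was taken between arrays of 1 day, and was 1263 without set 1 of day 0, 1032 and 992 without either day 4 array and 991 and 1010 without either day 8 array.

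Set 2 differed little from set 1. With day in the model 24 genes differed, 13 higher and 11 lower, and 0 by at least 2-fold (n = 6 arrays each). Ptpre (0.55 ± 0.07), Crabp1 (0.46 ± 0.10) and Mdh1 (0.38 ± 0.08) were higher in set 2, Ldlrad3 (-0.61 ± 0.09) and Wdr26 (-0.55 ± 0.11) were lower, and Gnai3 was at least 1.22-fold lower. None of the 11 pigment genes passed, with Tyr at 0.08 ± 0.06 and Mitf at -0.12 ± 0.06, and 0 of the tested gene lists shifted. Some of these directions depend on the set numbers. With the value table's set numbers alone, Ptpre (-0.039), Crabp1 (-0.15) and Gnai3 (0.12) changed sign, while Ldlrad3, Wdr26 and Mdh1 did not. With the value table, which changes both the values and the set numbers of 3 days, Ptpre (-0.042), Crabp1 (-0.20), Ldlrad3 (0.22), Wdr26 (0.060) and Gnai3 (0.25) changed sign. The count was 0 with that table, 0 with its set numbers alone and 0 with its values under the signal table's set numbers, where these genes kept their sign. With median centring it was 12, of which 2 were higher. Without 1 of the day 20 arrays it was 1, without 1 of the day 16 arrays 6, and without 1 array of day 0 or day 8 it was 9.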

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

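The tests of probes without a name and of an interaction were added after the main results were seen. Samples far from the rest of their group were sought by Dixon's test, a planned rule. It was run 144 times, each time on 1 gene, list or array measure within a state or a set. An array was flagged in 5 of these runs, fewer than the 1 in 20 that chance gives for independent arrays. Arrays of a state include pairs from 1 day, so they are not independent. Mc1r on the set 1 array of day 12 lay apart from the other 5 pigmented arrays, with 0.671 of the range between it and the nearest. Crabp1 on the day 20 array stood apart within set 1 (0.670), Tyrp1 on the day 20 array within set 2 (0.851), and Dct on the day 20 array within set 1 (0.756) and within set 2 (0.8025). Each set held 1 array per day, so an array apart within a set can reflect its day. By the probes used, both day 20 arrays were the lowest of the 12 for Dct (11.59 and 11.57) and for Tyrp1 (12.90 and 12.86). Those flags thus follow day 20 rather than a single array. Other Tyrp1 probes gave -0.69 and 0.096 for day 20 against day 0. No explanation was tested for Mc1r and Crabp1.

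Probes without a gene name were outside every comparison above. Of 3858 such detected probes 1856 (48.1%) changed between day 8 and day 0 in limma's test, 2010 between day 20 and day 12, and 304 between the labelled states. A difference of the pigmentation effect between set 1 and set 2, tested as an interaction in limma, gave 0 genes, with 36 at an unadjusted p under 0.05. That model had no term for day, so its spread included that between days. The 36 of 11470 genes are far below a share of 0.05, so the test could hardly call a gene. It does not show that the sets agree.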

How the results depend on the processing

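The alternatives were planned, except for those chosen after seeing the data: leaving out both arrays of day 20 or day 8, the set numbers of the value table, and its values with the signal table's set numbers. Counts for days against day 0 and for day 20 against day 12 stayed within 1.5 times under every alternative run, and the pigment list kept its direction and call at the preset correlation in every comparison except day 16 against day 12. There its median was -0.071 with the value table (camera adjusted p = 0.0976), -0.16 with probes detected on all arrays (0.172), -0.15 with the mean of probes (0.118), and -0.20 to -0.088 with 1 array left out. The count for day 16 against day 12 was 2833 with median centring. Array counts and signal over background limit these values, and the cause of a change under an alternative was not tested. The planned chip block was not run. An array left alone on its day was assumed to vary like the others.

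For pigmented against depigmented, 1938 genes became 5598 with array weights, 7585 with the mean of days in the model of all days, whose spread leaves out that between days, and 366 without both day 8 arrays. It lay between 991 and 2349 with 1 array left out, lowest without set 1 of day 8, and was 1263 without set 1 of day 0, 1032 and 992 without either day 4 array and 1010 without set 2 of day 8. With the set as a replicate block it was 1501. The block moved no count by over 1.5 times, changed the calls of 10 named genes and 2 lists, and changed no other call among them. More list calls changed with median centring (10), with the value table (9) and without both day 20 arrays (9). Without both day 8 arrays 1 list call changed, and without background correction 0. For set 2 against set 1, 24 genes became 12 with median centring, 0 with the value table and its exchanged set numbers, 2 without the detection filter, 1 with the mean of probes, 1 without the eBayes trend, 0 without day as a term, 1 without both day 20 arrays 0 with the value table's set numbers alone and 0 with its values under the signal table's set numbers. It lay between 1 and 24 with 1 array left out, at 9 without an array of day 0 or 8, 6 for day 16 and 1 for day 20.

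The correlation between day 8 against day 0 and day 20 against day 12 stayed negative: -0.153 without background correction, -0.171 with median centring, -0.157 with the value table, -0.157 without the detection filter, -0.112 with probes detected on all arrays, -0.172 with the mean of probes and -0.165 to -0.156 with 1 array left out. Lists called with an estimated correlation numbered 8 in place of 15 for day 16 against day 0, 6 in place of 12 for day 20 against day 0, and 1 in place of 15 for the labelled states.

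Over all settings, named genes kept their side of the threshold in 23612 results, lost the call in 492, gained it in 117 and changed sign in 21. A change of sign was counted among the 21 only where the main or the alternative value passed the threshold. Other changes of sign are among the 23612. Set 2 against set 1 changed sign with the value table and its set numbers for Ptpre (-0.042), Crabp1 (-0.20), Map1lc3b (-0.16), Ldlrad3 (0.22), Gnai3 (0.25), Wdr26 (0.060), Kdelr1 (0.12) and Ero1a (0.042), and with its set numbers alone for Ptpre (-0.039), Crabp1 (-0.15), Map1lc3b (-0.15), Gnai3 (0.12), Kdelr1 (0.075) and Ero1a (0.021). None of these genes changed sign with its values under the signal table's set numbers. With the mean of probes Ctnnb1 changed sign on day 8 (-0.025), day 12 (-0.10) and day 16 (-0.13) against day 0 and on day 20 against day 12 (0.026), Lyz2 on day 8 (0.21) and Mcm6 on day 12 (0.080). Hspa4l did so for day 16 against day 12 with probes detected on all arrays (0.16).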

Other observations

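The comparisons of neighbouring days and all tests of the 3 patterns weighed here were chosen after the results were seen, and the counts over other splits of the arrays were planned.

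Between day 8 and day 12, when pigment genes began to come down, several genes outside the pigment list also changed widely. Timp3, a protease inhibitor gene, rose by 4.44 ± 0.10, Txnip, a thioredoxin-interacting protein gene, by 4.30 ± 0.07, and Dbp, a clock output gene, by 3.52 ± 0.07 (limma log2 changes ± SE, n = 2 arrays per day). Id2 (-3.73 ± 0.08) and Sox9, a transcription factor gene (-2.70 ± 0.08), fell, as did Gpr143 (-3.13 ± 0.11) and Mitf (-2.83 ± 0.12) of the pigment list. In this step 6125 genes changed. Ribosome biogenesis genes fell in 23 of 24 cases (23 adjusted over the list alone; median -0.89, or -0.87 with bounds, camera adjusted p = 5.24e-11), sterol synthesis genes in 15 of 18 (15 adjusted over the list alone; median -1.23, or -1.18 with bounds, camera adjusted p = 5.25e-09) and DNA replication genes in 28 of 30 (28 adjusted over the list alone; median -0.88, camera adjusted p = 4.79e-12), while 17 of 22 hypoxia response genes rose (17, with 1 lower, adjusted over the list alone; median 0.56, camera adjusted p = 1.61e-05).

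Between day 16 and day 20, both labelled depigmented, 7454 genes changed. Pmel (-4.38 ± 0.07), Tyr (-2.75 ± 0.11) and Dct (-2.74 ± 0.08) fell, and 14 of 21 pigment genes fell while 3 rose (14 and 3 adjusted over the list alone; median -1.12, camera adjusted p = 0.000115). Interferon genes were higher in 13 of 39 cases and lower in 20 (14 and 20 adjusted over the list alone; median -0.24, camera adjusted p = 0.326). Fgf21, a hormone gene, was at least 15.8-fold higher, Gadd45a rose by 4.38 ± 0.12, and Mcm5 fell by 5.04 ± 0.08.

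Days 4 and 8 could not be separated, although every other pair of days differed widely. The standard deviation of the difference across genes was 0.126 between the days, 0.873 of the larger of the values from the 2 other ways of pairing the same 4 arrays (0.144 and 0.142). Too few arrays is argued against for changes of 2-fold, since 89 of 100 genes simulated with such a change between these days were called. Smaller changes were not simulated for these days. In the simulation of day 8 against day 0, 48% of changes of 0.5 log2 units were recovered, so small differences may have been missed. Cells in an unchanged state from day 4 to day 8 may give this, as could the same RNA hybridized under both labels, and no value here parts these.

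Interferon genes were lower on the pigmented day in 9 of 9 pairs of a pigmented and a depigmented day, by medians of -1.21 to -2.01, so no single day accounts for the difference. Leukocytes in the depigmented cultures are argued against, because 0 of 12 leukocyte markers were detected on all 6 depigmented arrays (10 of the 12 were on the array), and Lyz2 and Fcer1g, the markers detected most, were seen on more pigmented than depigmented arrays. Time since plating alone is argued against, since the list was lower at equal times by the protocol: by a median of -1.88 at 4 days (day 4 against day 16, 38 of 39 genes lower) and of -1.30 at 8 days (day 8 against day 20, 35 of 39). Seeding density may be involved and cannot be told apart from pigmentation: the day 0 arrays carried opposite density labels and differed by 0.00752 in the list's median, but those labels conflict with the protocol. Pigmentation itself and medium effects remain open as untested explanations.

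Cell cycle genes were lower on day 20 than on days 0, 12 and 16. Weaker signal on these arrays is argued against, since the G2 and M phase median of -3.33 between day 20 and day 12 lay below all 10000 random lists matched on mean expression (lowest -0.84). The choice of 1 probe per gene is also argued against, since the mean of all probes gave -2.36. A stop of proliferation at the density reached by day 20 is a hypothesis that may fit, and cell counts were not used here.

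Other splits of the arrays bear on 2 of the counts. Of 100 splits of the 12 arrays into 6 and 6, only the real one gave as many as its 1938 genes (highest other 0). Nearly all of the others parted arrays of 1 day, which resemble each other, so they would give few genes whatever the labels. No conclusion is drawn from these splits. Keeping days whole, 3 of the 10 splits gave as many genes, the real one included, and 10 splits are too few for a share under 0.05. Days 0, 12 and 20 against the rest gave 2867 and days 0, 12 and 16 against the rest 1941, both with days 4 and 8 on the same side as in the real split, while days 0, 4 and 8 against the rest gave 132 and the 6 splits that parted days 4 and 8 gave 0. The count therefore does not single out the labels. For the sets, only 1 of 32 exchanges of set numbers within days, the real one by the signal table's names, gave as many as 24 genes (highest other 1), so chance can be excluded for that count only as computed. It fell to 1 without either day 20 array, and to 0 with the value table's set numbers, with its values or with both.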
